A study of Homo sapiens with 9 samples.

How the data were processed

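The 9 libraries are total RNA from H1975 cells with a doxycycline-inducible dCas9-KRAB repressor, 3 with a non-targeting guide, 3 with gRNA1 and 3 with gRNA2 against the long noncoding RNA TRIDENT. Per the labels, the cells had 4 ug/ml doxycycline for 72 h, and libraries were made after ribosomal RNA depletion; the setting used for the strand is not stated. The authors quantified transcripts with Salmon 1.4.0 against hg38 and deposited 1 table per library. Its values are an estimated count of reads per transcript, per the file headers, and TPM computed by the authors' run, beside lengths and effective lengths. No other normalization had been applied to the deposited estimated counts, and TPM was used for the single transcripts of the target but in no test.

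Each table lists 211939 transcripts, of which 95.7% matched GENCODE 29 transcripts by identifier. Estimated counts were summed over 56823 genes and rounded, and the 1.26% to 1.33% of reads on unmatched transcripts were left out. Current symbols were found for 99.2% of the genes. TRIDENT was matched through its RefSeq record, listed under the symbol TRIDDENT. The start and end of that record are those of ENST00000576810.1, a transcript of the gene named AC005736.1 in GENCODE 29, and exons were not compared. Read totals ran from 16918432 to 26466536 per library. Intervals cover counting error and the spread between libraries as edgeR estimates it for folds, and counting error alone for shares and for ratios of summed reads.

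Groups followed the labels. In edgeR 4.0.16 (R 4.3.3), genes were kept by filterByExpr, which left 19658, libraries were scaled by TMM, and quasi-likelihood F tests compared each guide with the control and gRNA2 with gRNA1, two-sided, in a single fit of all 9 libraries. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The biological coefficient of variation was 0.051. The 34 gene lists, written before the data were examined, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes and then with the correlation estimated from the data, with adjustment over the 34 lists of each comparison. The values of 1 list and of some named genes are not described. The same edgeR p-values were also adjusted over each list alone. CPM, the counts scaled to a common library size, use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 did the sums, sequence comparisons and figures.

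The genes named were set by rules before the data were examined. They are the target with TRIM28, EGFR and further fixed genes that are not described; the 10 highest and 10 lowest genes changed with both guides, by the smaller change; up to 5 long noncoding RNAs lower with both; the 5 highest and 5 lowest of each comparison; and up to 4 members of each list with the lowest adjusted p. Apart from the first and last kinds, genes needed an average log2 CPM of at least 1 and all 3 libraries of a group beyond all 3 of the other, and bare clone names were skipped, except among the long noncoding RNAs. Only 1 long noncoding RNA met these rules among those lower with both. Because the rules gave more than 60 genes, not every list member is printed. TXNIP, SLC5A3, MRPS6, PSAT1, ASNS, PSG4, DNASE1 and ADCY9 were chosen after their values were seen.

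The effect of shared controls was measured in 20 simulations of all 9 libraries with no group effect. The test was tested on simulated data with known changes, made only in genes with an average log2 CPM of at least 1. Counts were drawn with the spread of the trend over level, and recovery at lower levels was not measured. Of genes changed 1.25-, 1.5- and 2-fold, 62.7%, 82.1% and 93.9% were recovered in the simulated comparison of gRNA1 with the control and 62.7%, 86.6% and 97% in that of gRNA2, with 0 and 9 false calls among 19337 and 19354 genes. Between the guides 52.2%, 86.6% and 97% were recovered, with 14 false calls among 19329 genes, and in the same direction with both guides 53.7%, 76.1% and 98.5%, with 0. With no change 0 genes and 0 lists were called. Each gene was drawn independently, so this run cannot show false list calls that arise when genes vary together. For named genes, the share of 31-mers found in transcripts of other genes on either strand was computed from the transcript sequences. Besides the shares given with the results, it was between 20.29% and 44.96% for MT-CO3, DDIT4, PGAM1, UHRF1, H2BC10, CYTOR, CFLAR, RRM2, DEPP1, CDC20 and ELF3, and below that for the other genes that the rules named and the results describe.

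The alternatives, chosen before the data were examined, were DESeq2 1.42.0, RLE scaling, no filter on low counts, a block for the replicate number, fits of only the 2 groups compared, offsets for the average transcript length, protein-coding genes alone, a change of at least 2-fold, the estimated correlation and leaving out each library in turn. A correction of each library for GC content and transcript length was added after the data were seen. Splits of the libraries into groups were refitted, with the real one included, 10 for each comparison of 2 groups and 100 for the genes shared by both guides, the rest of these drawn at random.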

Results

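Total RNA was sequenced from H1975, a human non-small cell lung cancer line with activating mutations of EGFR, carrying a doxycycline-inducible dCas9-KRAB repressor. The cells expressed a non-targeting guide RNA (control) or 1 of 2 guides against the long noncoding RNA TRIDENT, named gRNA1 and gRNA2, and had received 4 ug/ml doxycycline for 72 h. There were 3 groups of 3 libraries each. The controls had 19140677, 25178932 and 22393085 reads. The libraries labelled gRNA1 had 20331102, 23481019 and 20633783 reads, and those labelled gRNA2 had 24336262, 26466536 and 16918432. The most abundant gene in every library was MALAT1, a nuclear long noncoding RNA, with 3.18% to 3.98% of the reads. The labels do not say that the replicates of a group are separate cultures, so each p-value measures a difference against the spread between these libraries. Each comparison of a guide with the control asks which transcripts change when TRIDENT is the target of the repressor, and the comparison of the guides asks where they differ.

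The RNA matched to the target was at 0.745-fold in the libraries labelled gRNA1 and at 0.945-fold in those labelled gRNA2, and neither value passed the threshold after adjustment over all genes. The match rests on a RefSeq synonym, and the labels give no guide sequences to test it. TRIDDENT, the symbol that lists TRIDENT as a synonym (gene ENSG00000262185.2, chromosome 16, positions 3931217 to 3950586 of hg38, minus strand), had 2.58 ± 0.287 CPM (counts scaled to a common library size) in the controls, 1.91 ± 0.163 in the libraries labelled gRNA1 and 2.44 ± 0.132 in those labelled gRNA2 (mean ± SD, n = 3 each). The 95% interval of the fold was 0.588 to 0.943 with gRNA1 (unadjusted p = 0.0181, adjusted p = 0.128 over all genes), where all 3 libraries lay below all 3 controls, and 0.753 to 1.19 with gRNA2 (adjusted p = 0.81). These values rest on 49, 56 and 62 reads in the controls, 36, 49 and 38 in the libraries labelled gRNA1, and 61, 60 and 42 in those labelled gRNA2. The transcript ENST00000576810.1, which has the same start and end as the RefSeq TRIDDENT record, held 67.8% of these reads, and 12.61% of its 31-mers also occur in transcripts of other genes. Its level was 1.05 ± 0.0844 TPM in the controls, 0.99 ± 0.188 with gRNA1 and 1.1 ± 0.0676 with gRNA2, whereas ENST00000571302.1, with 29% of the reads, was at 1.54 ± 0.423, 0.78 ± 0.412 and 1.58 ± 0.221 TPM on an estimated 52.8, 26.1 and 52.8 reads per group. ENST00000649221.1, with 3.1% of the reads, was at 0.312 ± 0.0647, 0.0387 ± 0.067 and 0.063 ± 0.0552 TPM. The transcripts were not tested singly, so the fold of the gene is that of their sum. TRIM28, the scaffold protein of KRAB zinc finger repression named in the series title, had 420 ± 23.2 CPM in the controls. It had 383 ± 5.34 with gRNA1 (0.911-fold, adjusted p = 0.132) and 340 ± 25.8 with gRNA2 (0.809-fold, adjusted p = 0.00227). With a transcript length offset the TRIM28 call with gRNA2 ended. TRIM28 also passed the threshold with gRNA1 without a filter on low counts, or with a correction for GC content and length that was added after the data were seen. EGFR had 542 ± 9.37 CPM in the controls, 499 ± 3.75 with gRNA1 (0.92-fold, adjusted p = 0.0254) and 530 ± 8.19 with gRNA2 (0.977-fold, adjusted p = 0.548). The EGFR call with gRNA1 ended without any 1 of the 3 controls, gRNA1 replicate 1, gRNA1 replicate 2 or gRNA2 replicate 2 (adjusted p between 0.06 and 0.149). It also ended with the transcript length offset or with protein-coding genes alone.

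**Figure D1:**
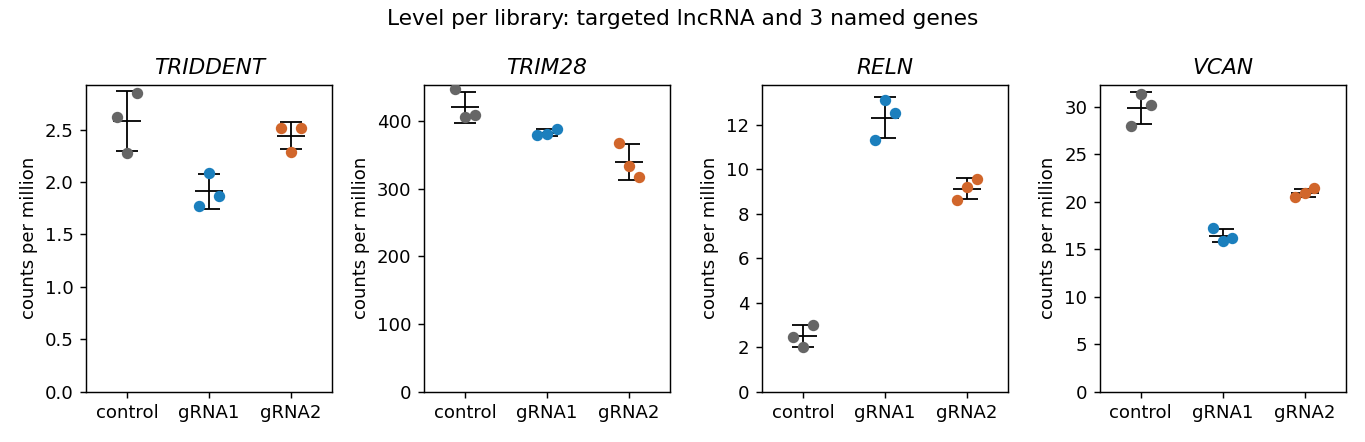
CPM of TRIDDENT, TRIM28, RELN and VCAN in each library (points), with the mean and SD of the 3 libraries of each group (bars); every vertical axis starts at 0. TRIDDENT in the libraries labelled gRNA2 lies at 2.44 ± 0.132 beside 2.58 ± 0.287 in the controls, whereas RELN is higher and VCAN lower in all 6 guide libraries than in the 3 controls.

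In the libraries labelled gRNA1, mainly genes of modest change moved, and most of the large changes were increases. RELN, the secreted glycoprotein reelin, rose from 2.48 ± 0.497 to 12.3 ± 0.902 CPM (4.99-fold, adjusted p = 1.22e-07, n = 3). ABCA12, an epidermal lipid transporter, rose 4.26-fold (adjusted p = 0.000165), the transcription factor SOX2 4.03-fold (2.89e-05), the tetraspanin TSPAN12 3.6-fold (2.21e-06) and MAOA, a monoamine oxidase, 3.43-fold (2.46e-05). ABCA12 and SOX2 rose from few reads, with 13, 23 and 18 reads of ABCA12 and 19, 17 and 22 of SOX2 in the controls. MMP13, a collagenase, rose 2.84-fold (adjusted p = 8.65e-08), and ABCC2, an organic anion efflux pump, 2.42-fold (8.65e-08). The proteoglycan VCAN fell from 29.8 ± 1.7 to 16.4 ± 0.687 CPM (0.549-fold, adjusted p = 2.38e-06). PXDN, a matrix peroxidase, fell to 0.544-fold (0.0019) and CALB1, a calcium-binding protein, to 0.55-fold (0.0105). ISY1-RAB43, a readthrough transcript, was at 0.563-fold (adjusted p = 0.0392) and CFB, complement factor B, at 0.578-fold (0.019), but 99.4% and 57.0% of their 31-mers also occur in other genes. Of 19658 genes tested with edgeR, 1391 passed an adjusted p of 0.05, 687 higher and 704 lower, and 97 of them changed at least 2-fold, 89 higher and 8 lower. With the transcript length offset the count was 538, and the calls of ISY1-RAB43 and CFB ended, as did that of ISY1-RAB43 with DESeq2. Leaving out control replicates 1, 2 or 3 gave 826, 786 or 727 genes, and leaving out gRNA1 replicates 1 or 2 gave 756 or 654. The CFB call ended without control replicate 1 or any of the 3 gRNA1 libraries (adjusted p between 0.0572 and 0.0751), and that of ISY1-RAB43 without any 1 of the 3 controls or gRNA1 replicates 1 or 3 (0.0668 to 0.13).

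Among the 34 gene lists set before the data were examined, genes of the ATF4 pathway and unfolded protein response, of sterol synthesis, of TGF-beta and YAP output and of the interferon response were lower in the libraries labelled gRNA1. For ATF4 and the unfolded protein response, 10 of 33 measured members fell (16 adjusted over the list alone), the median log2 change was -0.13 (adjusted p = 8.2e-11), and HSPA5, the chaperone BiP, fell to 0.828-fold (0.000163). For cholesterol and sterol synthesis, 9 of 24 members fell (11 adjusted over the list alone; list adjusted p = 2.83e-07). Examples are DHCR7 (0.809-fold, adjusted p = 0.00196), INSIG1 (0.832-fold, 0.00255) and HMGCS1 (0.854-fold, 0.00303). Among TGF-beta and YAP targets 12 of 24 fell and 1 rose (12 and 3 adjusted over the list alone), with a median log2 change of -0.17 (adjusted p = 1.41e-05). CCN1 was at 0.827-fold (adjusted p = 0.000357), FSTL1 at 0.802-fold (0.000694) and the riser CCN2 at 1.38-fold (0.00284). Among interferon-stimulated genes 9 of 38 fell and 1 rose (13 and 2 adjusted over the list alone; list adjusted p = 4.17e-06), with IFITM1 at 0.793-fold (0.000171), IFIT2 at 0.797-fold (0.0023) and RSAD2 at 0.729-fold (0.0061). These 4 list calls held with an estimated correlation between genes (adjusted p between 0.0167 and 0.0479). In all 3 libraries labelled gRNA1 the mean of the ATF4 list lay below every control, between -0.166 and -0.145 on the log2 scale relative to the control mean. The sterol list and the TGF-beta and YAP list also lay below every control. The interferon list did not separate the libraries, since gRNA1 replicate 3 and control replicate 3 both lay at -0.065.

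The other 11 lists past the threshold with gRNA1, of which 10 are described, passed only with the preset correlation. MAPK pathway output had 10 of 30 members lower and 1 higher (10 and 2 adjusted over the list alone; list adjusted p = 0.00246, adjusted p = 0.169 with an estimated correlation). In it the transcription factor MYC fell to 0.806-fold (adjusted p = 0.000543), while the EGFR ligand EREG rose 1.38-fold (0.00101). Hypoxia and glycolysis had 7 of 26 lower and 1 higher (9 and 2 adjusted over the list alone; 0.00113, adjusted p = 0.0955 with an estimated correlation), with the hexokinase HK2 at 0.76-fold (1.42e-05). Epithelial genes had 8 of 26 lower and 1 higher (10 and 1 adjusted over the list alone; 4.15e-05, adjusted p = 0.276 with an estimated correlation). The transcription factor ELF3 rose 1.35-fold (0.000691). Antigen presentation had 4 of 18 lower (4 adjusted over the list alone; 0.00469, adjusted p = 0.0763 with an estimated correlation), with the chaperone CALR at 0.797-fold (0.000148). Its list mean in control replicate 3 (log2 -0.155 from the control mean) lay below those in gRNA1 replicates 2 and 3 (-0.059 and -0.114). Fatty acid synthesis had 2 of 15 lower, SCD and FADS2 (4 adjusted over the list alone; 0.000781, adjusted p = 0.0697 with an estimated correlation), with the desaturase SCD at 0.826-fold (2.7e-05). DNA damage signalling had 3 of 25 lower and 1 higher, the same numbers adjusted over the list alone (0.0227, adjusted p = 0.171 with an estimated correlation), with the kinase WEE1 at 0.82-fold (0.00237). Cytosolic ribosomal proteins had 1 of 83 lower and 1 higher (0 adjusted over the list alone; 0.00607, adjusted p = 0.184 with an estimated correlation). G2 and mitosis had 1 of 36 lower (1 adjusted over the list alone; 0.0477, adjusted p = 0.26 with an estimated correlation). Mitochondrially encoded protein genes had 3 of 13 higher (7 adjusted over the list alone; 1.41e-05, adjusted p = 0.296 with an estimated correlation), with MT-CYB, cytochrome b, at 1.25-fold (0.000455). Without gRNA1 replicate 3, which had 6.53% of its reads on mitochondrial genes against 5.64% and 5.74% in the other gRNA1 libraries, the median log2 change of this list was 0.08 in place of 0.17 (adjusted p = 0.00314). Basal, squamous and neuroendocrine genes had 2 of 9 higher (2 adjusted over the list alone; 0.0215, adjusted p = 0.142 with an estimated correlation), SOX2 and SERPINB5. The SERPINB5 call ended without control replicate 1 or gRNA1 replicate 1 (0.0592 and 0.0754), and that of FADS2 without control replicates 1 or 3 or gRNA1 replicates 1 or 2 (0.0558 to 0.0854). The transcript length offset ended the gRNA1 calls of HMGCS1, FSTL1, FADS2 and SERPINB5. With protein-coding genes alone the ribosomal (adjusted p = 0.224), DNA damage signalling (0.195) and G2 and mitosis (0.31) calls ended. The last also ended without control replicates 2 or 3, gRNA1 replicates 2 or 3 or gRNA2 replicates 1 or 2 (0.0537 to 0.0962), and with a replicate block (0.0522) or RLE normalization (0.0508).

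The remaining 19 lists did not pass with gRNA1. Counted as members higher and lower, with the same counts adjusted over the list alone after them, homologous recombination had 1 and 0 of 28, then 1 and 0 (list adjusted p = 0.903). Non-homologous end joining had 0 and 1 of 19, then 0 and 2 (0.172). The Fanconi anaemia pathway had 0 and 0 of 18, then 0 and 0 (0.325), and excision and mismatch repair 0 and 2 of 28, then 0 and 2 (0.0677). S phase and DNA replication had 1 and 1 of 33, then 1 and 1 (0.903). Replication-dependent histones had 1 and 0 of 62, then 1 and 0 (0.325), and heat shock proteins 0 and 1 of 16, then 0 and 2 (0.104). KRAB zinc finger cofactors and heterochromatin had 1 and 0 of 22, then 1 and 0 (0.726). Zinc finger genes named ZNF had 5 and 6 of 478, then 1 and 0 (0.359), and nuclear oxidative phosphorylation 2 and 2 of 78, then 1 and 2 (0.104). NRF2 targets had 2 and 1 of 24, then 3 and 2 (0.101). Mesenchymal genes had 0 and 2 of 20, then 1 and 2 (0.176), and apoptosis regulators 3 and 1 of 29, then 4 and 5 (0.721). Long noncoding RNAs with known names had 4 and 5 of 21, then 5 and 6 (0.436), and markers of blood and stromal cells 1 and 0 of 10, then 1 and 0 (0.172). The median, mean and test differed in sign in the last 4 lists. EGFR family and ligands had 1 and 4 of 15, then 4 and 7 (median log2 -0.1, mean 0.07, direction down, 0.216). Drug efflux transporters had 2 and 2 of 12, then 2 and 2 (-0.05, 0.15, up, 0.104). Alveolar and club cell genes had 0 and 0 of 13, then 0 and 0 (0.11, -0.03, up, 0.451). NF-kB and inflammatory genes had 1 and 3 of 17, then 1 and 3 (0.04, 0.02, down, 0.421). Without 1 library or in another setting, 6 of the 19 lists crossed the threshold in at least 1 case. Excision and mismatch repair did so without gRNA1 replicates 1 or 3 (0.0414 and 0.0457) and heat shock proteins without gRNA1 replicate 3 (0.0406). Oxidative phosphorylation did so without control replicate 2 (0.0493), gRNA1 replicate 1 (0.0417) or gRNA1 replicate 2 (0.0442), or with the GC correction (0.00287). Histones, as higher, passed without control replicate 1 (0.0496), NRF2 targets with protein-coding genes alone (0.0284), and known long noncoding RNAs with the GC correction (0.0118).

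In the libraries labelled gRNA2, genes of cell division, replication-dependent histones and glycolysis were lower, and the MAPK output list was higher, as were some genes of the ATF4 pathway. CCNB1, the mitotic cyclin, fell from 90 ± 0.721 to 61.1 ± 1.16 CPM (0.678-fold, adjusted p = 4.89e-06, n = 3), the proliferation marker MKI67 to 0.731-fold (1.39e-05), and LDHA, lactate dehydrogenase, to 0.674-fold (2.66e-07). The linker histone H1-5 fell from 23.8 ± 2.14 to 11.8 ± 0.433 CPM (0.497-fold, adjusted p = 3.54e-06). The core histones also fell, H3C2 to 0.559-fold (3.12e-05), H3C1 to 0.561-fold (0.0165), H2BC10 to 0.563-fold (0.000274) and H2BC14 to 0.577-fold (0.00769). CHAC1, a glutathione-degrading enzyme induced by ATF4, rose from 2.63 ± 0.441 to 6.06 ± 0.241 CPM (2.29-fold, adjusted p = 0.000172). RELN rose 3.68-fold (1.95e-06), HAGLR, a long noncoding RNA of the HOXD cluster, 2.43-fold (0.000149), ENTREP1 2.38-fold (3.54e-06) and RP1, a microtubule-associated protein, 2.34-fold (0.00455). In edgeR 1659 genes passed the threshold, 726 higher and 933 lower, of which 46 changed at least 2-fold, 36 higher and 10 lower. With the transcript length offset the count was 434 and the calls of H3C1, H2BC14, HAGLR and RP1 ended. The H3C1 call also ended without control replicate 3 (adjusted p = 0.062) and that of H2BC14 without gRNA2 replicate 2 (0.0596). Leaving out control replicates 1, 2 or 3 gave 1023, 900 or 792 genes, and leaving out gRNA2 replicate 2 gave 671. Without gRNA2 replicate 3, the shallowest library, which stood apart from the rest on the second principal component, the count was 1144.

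The G2 and mitosis list had 32 of 36 members lower with gRNA2 (35 adjusted over the list alone), with a median log2 change of -0.34 (adjusted p = 3.63e-54), TPX2 at 0.766-fold (6.08e-05) and the APC activator CDC20 at 0.695-fold (0.00011). S phase and DNA replication had 18 of 33 lower (20 adjusted over the list alone; adjusted p = 8.29e-17). The replication clamp PCNA was at 0.759-fold (0.000774), UHRF1 at 0.785-fold (0.000748) and RRM2 at 0.811-fold (0.000886). Among replication-dependent histones 43 of 62 fell and 1 rose (54 and 1 adjusted over the list alone), with a median log2 change of -0.47 (2.39e-40). Hypoxia and glycolysis had 15 of 26 lower and 1 higher (18 and 2 adjusted over the list alone; 1.2e-25), with NDRG1 at 0.651-fold (1.31e-05) and PGAM1 at 0.751-fold (2.01e-05). The means of these 4 lists lay below all 3 controls in all 3 libraries labelled gRNA2, and the calls held with an estimated correlation (adjusted p between 0.000711 and 0.00723). MAPK pathway output had 8 of 30 higher (15 higher and 2 lower adjusted over the list alone; 6.6e-10), with EGR1, an immediate early transcription factor, at 1.7-fold (1.21e-06), EREG at 1.83-fold (5.3e-06) and MYC at 1.4-fold (1.15e-05). The ATF4 and unfolded protein response list was split, with 13 of 33 higher and 5 lower (15 and 6 adjusted over the list alone; median log2 0.09, 1.58e-06, and median log2 0.05 without gRNA2 replicate 1). The ATF4 and stress factors DDIT3 (1.8-fold, 1.15e-05), ATF3 (1.58-fold, 1.66e-05) and DDIT4 (1.59-fold, 2.24e-05) rose, whereas the chaperone HSPA5 was at 0.917-fold (0.0252). That HSPA5 call ended without control replicates 2 or 3 or gRNA2 replicates 1 or 2 (adjusted p between 0.0595 and 0.145). The calls of HSPA5 and RRM2 ended with the transcript length offset. The calls of both lists held with an estimated correlation (0.0195 and 0.0326).

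A further 10 lists passed with gRNA2 under both correlations. Cytosolic ribosomal proteins had 22 of 83 lower (46 lower and 1 higher adjusted over the list alone; 1.84e-13), with RPSA at 0.844-fold (0.000319) and RPL6 at 0.892-fold (0.00451). Nuclear oxidative phosphorylation had 21 of 78 lower (32 adjusted over the list alone; 2.73e-11), with ATP5F1A at 0.884-fold (0.00673). Heat shock proteins had 8 of 16 lower (10 lower and 2 higher adjusted over the list alone; 2.22e-06), with HSPH1 at 0.797-fold (0.000484) and HSPA8 at 0.835-fold (0.000675). KRAB zinc finger cofactors and heterochromatin had 7 of 22 lower (8 adjusted over the list alone; 9.07e-06), with HDAC1, a deacetylase, at 0.793-fold (0.000249) and the methyltransferase SUV39H1 at 0.739-fold (0.00607) beside TRIM28. DNA damage signalling had 6 of 25 lower (9 adjusted over the list alone; 0.000223), with the remodeller CHD4 at 0.863-fold (0.00203). Non-homologous end joining had 5 of 19 lower (5 adjusted over the list alone; 0.00349), with XRCC6 (Ku70) at 0.835-fold (0.000748), XRCC5 (Ku80) at 0.866-fold (0.00549) and POLQ at 0.842-fold (0.00536). Fatty acid synthesis had 6 of 15 lower (9 adjusted over the list alone; 5.43e-05), with SCD at 0.876-fold (0.000677). Cholesterol and sterol synthesis had 4 of 24 lower (7 adjusted over the list alone; 0.00218). NRF2 targets had 8 of 24 lower and 2 higher (12 and 3 adjusted over the list alone; 0.00735), with the haem oxygenase HMOX1 at 0.767-fold (0.00136) and ABCC2 at 1.69-fold (1.53e-05). EGFR family and ligands had 3 of 15 higher, EREG, AREG and ERRFI1 (3 adjusted over the list alone; median log2 0, mean 0.17, 0.00555). EREG and AREG also belong to the MAPK output list, so the calls of these lists overlap. The transcript length offset ended the calls of ATP5F1A, TRIM28, HDAC1, CHD4, XRCC6, XRCC5, POLQ and ERRFI1. Of the genes named in these lists, CHD4, XRCC6, RPSA, HSPA8 and RPL6 share 55.6%, 27.97%, 27.49%, 21.5% and 20.74% of their 31-mers with other genes.

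Another 9 lists passed with gRNA2 under the preset correlation alone. TGF-beta and YAP targets had 5 of 24 higher and 2 lower (5 and 3 adjusted over the list alone; median log2 0.01, 0.0157, adjusted p = 0.0858 with an estimated correlation), with CCN1 at 1.43-fold (1.46e-06), CCN2 at 2.13-fold (1.95e-06) and FSTL1 at 0.88-fold (0.0182; not without control replicates 1 or 3 or gRNA2 replicate 2, 0.0685 to 0.114). Mitochondrially encoded protein genes had 5 of 13 higher (8 adjusted over the list alone; 1.29e-05, adjusted p = 0.266 with an estimated correlation), with MT-CO3 at 1.23-fold (0.000223). Homologous recombination had 2 of 28 lower and 1 higher (8 and 3 adjusted over the list alone; 0.0474, adjusted p = 0.328 with an estimated correlation), with the single-strand binding protein RPA1 at 0.86-fold (0.00319). The Fanconi anaemia pathway had 2 of 18 lower, FANCD2 and UBE2T (3 adjusted over the list alone; 0.0203, adjusted p = 0.116 with an estimated correlation). The FANCD2 call ended without any 1 library but gRNA1 replicate 3 (0.0506 to 0.147), and that of UBE2T without any 1 but control replicate 1 or gRNA2 replicate 1 (0.0526 to 0.169). Excision and mismatch repair had 5 of 28 lower (6 adjusted over the list alone; 0.0104, adjusted p = 0.0555 with an estimated correlation), with the flap endonuclease FEN1 at 0.75-fold (0.0106). Apoptosis regulators had 2 of 29 higher (2 adjusted over the list alone; 0.0293, adjusted p = 0.0676 with an estimated correlation), CFLAR, an inhibitor of caspase-8 (1.33-fold, 6.22e-06), and PMAIP1, the BH3-only protein NOXA (1.37-fold, 0.00157). Basal, squamous and neuroendocrine genes had 3 of 9 higher (3 adjusted over the list alone; 0.0167, adjusted p = 0.0676 with an estimated correlation), SOX2, PAX9 and POU2F3 (the last not without control replicates 1 or 3 or gRNA2 replicate 2, 0.0526 to 0.0704). Epithelial genes had 2 of 26 lower and 1 higher (5 and 2 adjusted over the list alone; 0.0432, adjusted p = 0.563 with an estimated correlation), with KRT19 at 0.817-fold (0.00187). Long noncoding RNAs with known names had 5 of 21 higher (6 higher and 1 lower adjusted over the list alone; median log2 0.01, mean -0.03, direction up, 0.0417, adjusted p = 0.0858 with an estimated correlation), with NEAT1 at 1.22-fold (8.34e-06). With protein-coding genes alone the excision repair (adjusted p = 0.0762), Fanconi anaemia (0.0975), homologous recombination (0.221) and epithelial (0.185) calls ended. The epithelial (0.239) and long noncoding RNA (0.388) calls ended with the GC correction, and that of homologous recombination with a replicate block (0.0608). The transcript length offset ended the calls of FSTL1, RPA1, FANCD2, UBE2T, FEN1, PAX9 and POU2F3. Those of UBE2T and POU2F3 also ended with DESeq2, those of FANCD2 and UBE2T with only the 2 groups compared, that of FANCD2 with protein-coding genes alone, and that of UBE2T with a replicate block or without a filter. The call for apoptosis regulators ended without control replicate 2 (0.0546) or gRNA2 replicate 2 (0.0517), and that for epithelial genes without control replicate 1 (0.357) or gRNA2 replicates 2 (0.0821) or 3 (0.368). The call for homologous recombination ended without control replicates 2 (0.208) or 3 (0.068) or gRNA2 replicate 1 (0.295). That for known long noncoding RNAs ended without control replicates 1 or 2, gRNA1 replicate 2 or gRNA2 replicates 2 or 3 (0.0517 to 0.0922).

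Of the 9 lists below the threshold with gRNA2, 8 are given in the same form, members higher and lower, then the counts adjusted over the list alone. Interferon-stimulated genes had 4 and 3 of 38, then 5 and 5 (0.86). NF-kB and inflammatory genes had 1 and 1 of 17, then 3 and 1 (0.408). Mesenchymal genes had 2 and 2 of 20, then 2 and 2 (0.493), in which the matrix proteins FN1 (1.31-fold, 1.38e-05) and TGFBI (0.823-fold, 6.23e-05) moved apart. Markers of blood and stromal cells had 1 and 0 of 10, then 1 and 0 (0.153), the riser with both guides being CDH5 (3.19-fold with gRNA1, adjusted p = 0.000945, and 2.39-fold with gRNA2, 0.00689). Zinc finger genes named ZNF had 15 and 10 of 478, then 13 and 7 (0.793), with ZNF114 at 0.712-fold (1.15e-05) and ZNF419 at 1.26-fold (0.000273). Signs of median, mean and test differed in antigen presentation and drug efflux. Antigen presentation had 1 and 2 of 18, then 2 and 3 (median log2 0.06, mean -0.07, direction down, 0.793), and drug efflux transporters 1 and 2 of 12, then 2 and 2 (-0.05, 0.07, up, 0.748). Alveolar and club cell genes had 2 and 1 of 13, then 2 and 2 (0.98). GDF15, a stress-induced cytokine, rose 1.77-fold (7.76e-05).

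**Figure D2:**
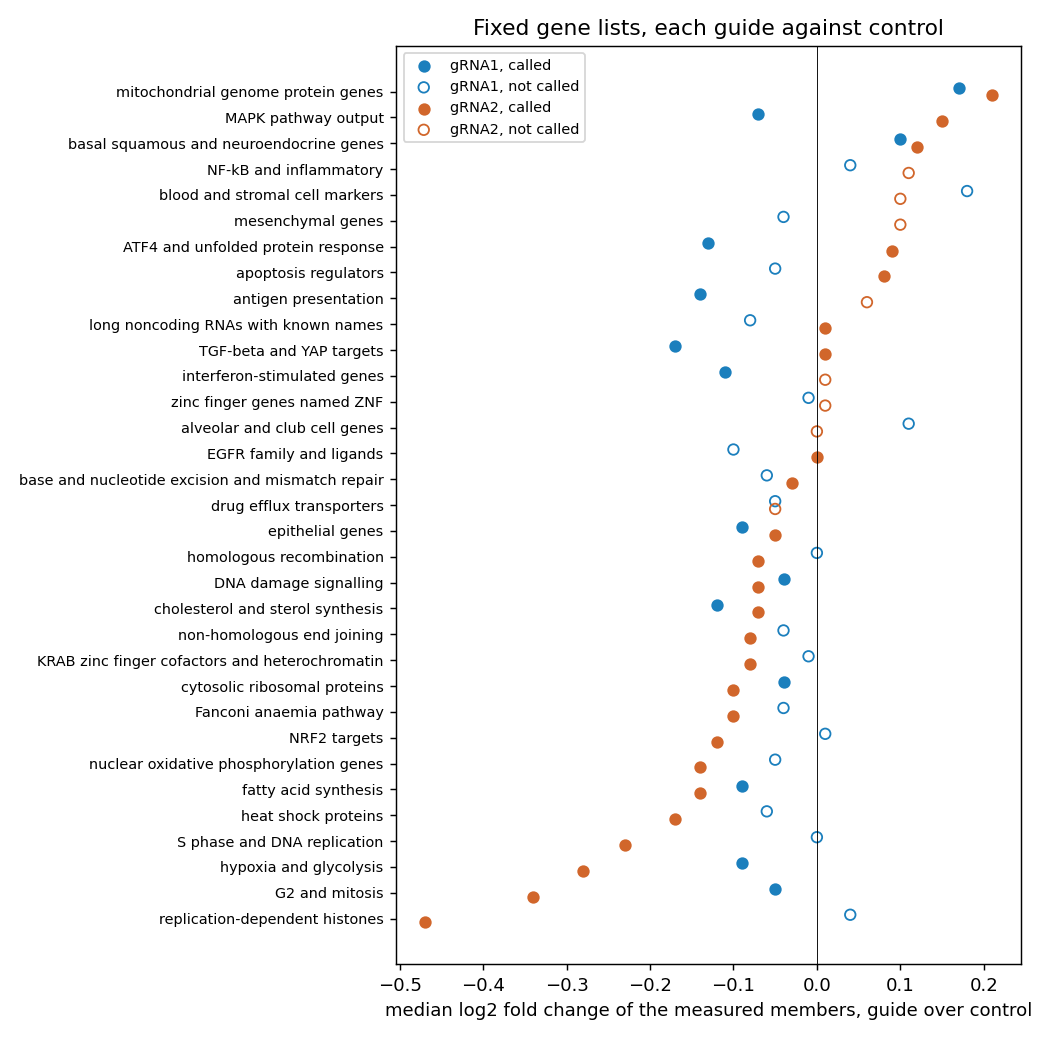
Median log2 fold change over control of the measured members of 33 of the 34 gene lists, for gRNA1 (blue) and gRNA2 (orange); filled points passed an adjusted p of 0.05 with the preset correlation. Histones, at -0.47, and G2 and mitosis, at -0.34, are the lowest medians with gRNA2.

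**Figure D3:**
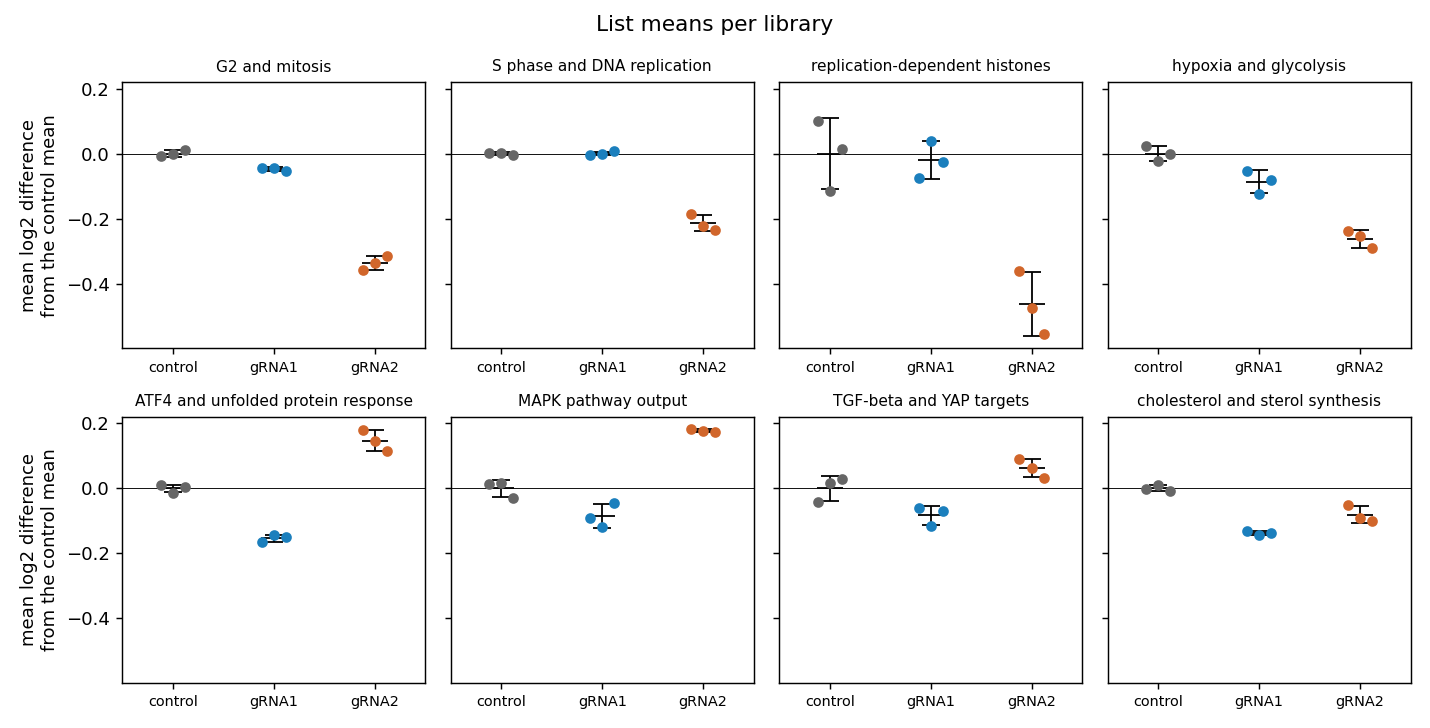
Mean log2 difference from the control mean over the members of 8 lists in each library (points), with the mean and SD of each group of 3 libraries (bars). The ATF4 list lies at -0.154 in the libraries labelled gRNA1 and at 0.146 in those labelled gRNA2.

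With both guides, 484 genes passed the threshold in the same direction, 290 higher and 194 lower. The larger part was lower with DESeq2 (213 higher and 246 lower) and with the GC correction (392 and 1061). RELN, HAGLR, ENTREP1, RP1, ABCA12 and SOX2 were at least 2-fold higher with each guide, as were PTPN13, a phosphatase (2.91-fold with gRNA1 and 2.15-fold with gRNA2), the cytokine IL24 (2.47 and 2.15), FAM230J (2.42 and 2.1) and MAOA (3.43 and 2.09). For the 10 largest rises the adjusted p was at most 0.00464 with gRNA1 and 0.015 with gRNA2. FAM230J shares 85.0% of its 31-mers with other genes. Among these 10, ABCA12, SOX2, RP1, PTPN13 and FAM230J had only 13 to 33 reads in each control library. The 10 largest falls were those of VCAN (0.549 and 0.7), PXDN (0.544 and 0.713), MGP, the matrix Gla protein (0.741 and 0.749), LTBP1, which binds latent TGF-beta (0.715 and 0.79), EPDR1 (0.7 and 0.732), MBOAT7, a phospholipid acyltransferase (0.636 and 0.75), the chloride transporter CLCN4 (0.749 and 0.779), PPIF, cyclophilin D of mitochondria (0.77 and 0.782), DEPP1 (0.793 and 0.774) and ARL14EPL (0.719 and 0.794), with adjusted p at most 0.0209 with gRNA1 and 0.0375 with gRNA2. CFLAR (1.29 and 1.33) and CYTOR (1.15 and 1.27) were also higher with both, and SCD and CALR lower. Independent lists of these sizes would share 58.8 genes in the same direction, but both comparisons use the same controls, and in 20 simulations with no effect and shared controls edgeR called 0 genes the same way. At an unadjusted p of 0.05, 1872 genes moved the same way, against a mean of 180.1 and a highest of 206 in the simulations. The fold changes correlated across genes, which are not independent replicates, at r = 0.535 against a simulated mean of 0.498. No group had changes of its own in these simulations. They therefore cannot show how many shared calls the common controls give when the groups do differ. With the libraries labelled gRNA2 as the reference in place of the control, 491 genes moved the same way in the other groups. Under the transcript length offset 104 genes were shared, 80 higher and 24 lower. The calls of RP1, PTPN13, IL24, VCAN, EPDR1, CLCN4 and LTBP1 then ended with both guides. Those of HAGLR, ABCA12, MAOA, MGP, MBOAT7 and CALR ended with gRNA2, and those of DEPP1, CYTOR and CFLAR with gRNA1. PXDN with gRNA2 also missed the threshold with DESeq2 and with a replicate block. Without control replicates 1, 2 or 3 the count was 263, 252 or 216. Without gRNA1 replicates 1 or 2 it was 299 or 256, without gRNA2 replicate 2 it was 222, and without gRNA2 replicate 3 it was 356.

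Several of these shared calls lie close to the threshold, in all but 2 genes through gRNA2 alone. The gRNA2 call of ABCA12 ended without control replicates 1 or 3 (adjusted p = 0.0537 and 0.0552). Without 1 library the gRNA2 call also ended for FAM230J (control replicate 3 and gRNA2 replicate 2, 0.0664 and 0.0596), EPDR1 (gRNA2 replicate 2, 0.0519) and LTBP1 (control replicate 2 and gRNA2 replicate 2, 0.0571 and 0.0572). The same held for ARL14EPL (control replicates 2 and 3 and gRNA2 replicates 1 and 2, 0.0751 to 0.113) and PXDN (any control, gRNA1 replicate 2 or any gRNA2 library, 0.0544 to 0.166). For CLCN4 the gRNA1 call ended without control replicate 3 or gRNA1 replicate 2 (0.0611 and 0.0631) and the gRNA2 call without control replicate 3 or gRNA2 replicates 2 or 3 (0.0631 to 0.102). For DEPP1 the gRNA1 call ended without any control or gRNA1 replicates 1 or 2 (0.0564 to 0.104) and the gRNA2 call without gRNA2 replicate 2 (0.0687).

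**Figure D4:**
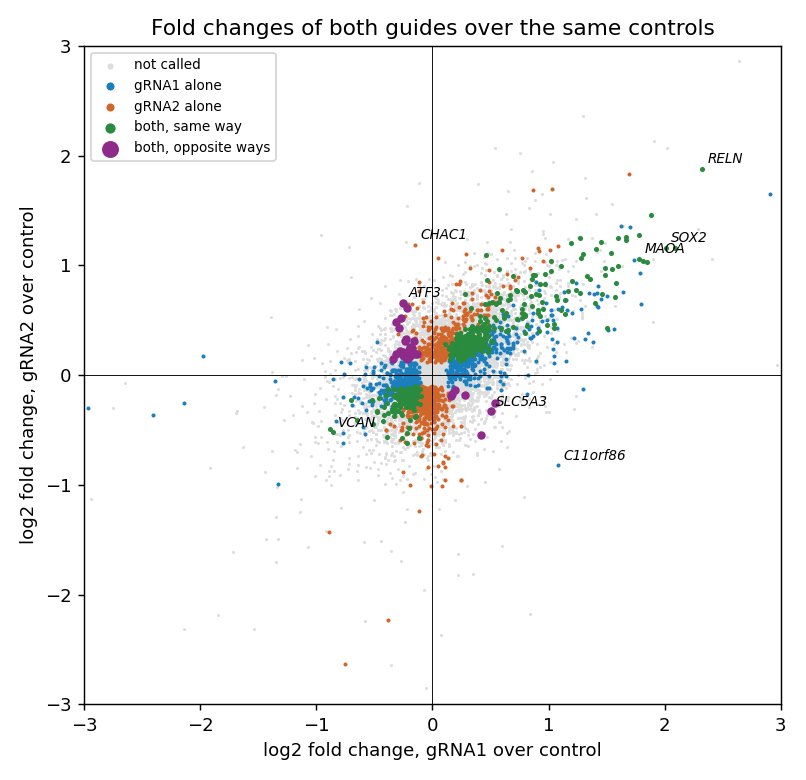
Log2 fold change over control with gRNA1 (horizontal) and with gRNA2 (vertical) for each tested gene, coloured by the comparison in which it passed an adjusted p of 0.05; 23 genes, 10 of them past the threshold in a comparison, lie beyond the axes at 3 and are not drawn. The 484 genes called the same way (green) lie in the upper right and lower left, and the 30 called opposite ways (purple) in the other quadrants.

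Long noncoding RNAs past the threshold were mostly higher with each guide: 141 higher and 11 lower of 3921 tested with gRNA1 and 159 and 12 with gRNA2, whereas protein-coding calls leaned the other way. These were 514 higher and 685 lower of 14018 with gRNA1, and 535 and 913 with gRNA2. In a fit of protein-coding genes alone, they were 662 higher and 511 lower with gRNA1 and 727 and 740 with gRNA2. Over all tested long noncoding RNAs 69.2% had a fold above 1 with gRNA1 and 70.8% with gRNA2, with median log2 changes of 0.12 and 0.14. The share of reads of protein-coding genes in transcripts annotated as retained introns was also higher, at 7.19% ± 0.01 and 7.51% ± 0.0586 against 6.98% ± 0.02 in the controls. HAGLR and FAM230J were among the 10 largest rises with both guides, and NEAT1, the abundant scaffold of paraspeckles, rose from 19500 ± 327 CPM to 21100 ± 502 with gRNA1 (1.08-fold, adjusted p = 0.00963) and 23800 ± 305 with gRNA2 (1.22-fold). Of the few that fell with both guides, SNHG29, a snoRNA host transcript, was the only 1 that met the criteria for naming (0.894-fold, adjusted p = 0.00589, and 0.928-fold, 0.0443). Among known long noncoding RNAs, LUCAT1 rose (1.4-fold, 0.000552) and SNHG1 fell (0.815-fold, 0.000807) with gRNA1. The SNHG29 call with gRNA2 ended without any 1 of 8 libraries, all but gRNA1 replicate 3 (adjusted p between 0.0545 and 0.167) and with only the 2 groups compared in each fit. With the transcript length offset the SNHG29 calls ended with both guides, and that of NEAT1 with gRNA1. The NEAT1 call with gRNA1 ended without gRNA1 replicates 1 or 2 (0.0609 and 0.0631), and turned to a log2 change of -0.02 with the GC correction.

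Set directly against each other, the guides differed in cell division, histones, glycolysis, the ATF4 pathway and MAPK output. CHAC1 was 2.53-fold higher in the libraries labelled gRNA2 than in those labelled gRNA1 (adjusted p = 8.5e-05), and the amino acid transporter SLC43A1 2.03-fold (0.00317). The stress transcription factors DDIT3 and ATF3 were 1.96-fold (3.6e-06) and 1.88-fold (9.22e-07) higher, and CFB 1.88-fold (0.0082). C11orf86 was at 0.268-fold (adjusted p = 0.000225), H2AC19 at 0.432-fold (0.0141), the long noncoding RNA MANCR at 0.465-fold (0.00917), H1-5 at 0.47-fold (9.22e-07) and MMP13 at 0.474-fold (1.36e-06). H2AC19 shares 97.2% of its 31-mers with other genes, and DDIT3 28.9%. The call of H2AC19 ended without gRNA1 replicate 1 (adjusted p = 0.0738) or gRNA2 replicate 2 (0.0896), and that of MANCR without gRNA1 replicate 1 (0.0505) or gRNA2 replicate 2 (0.0591). Both ended with the transcript length offset (0.0756 and 0.141). MMP13 rose with each guide against the control, 2.84-fold and 1.34-fold, the latter with an adjusted p of 0.0509 without gRNA2 replicate 2 and past the threshold no longer with the transcript length offset. In edgeR 1222 genes passed, 613 higher and 609 lower with gRNA2, and 30 changed at least 2-fold, 7 higher and 23 lower. Among the 877 genes called with gRNA1 alone 299 also differed between the guides, as did 440 of the 1145 called with gRNA2 alone. Another 30 genes were called in opposite directions, lower with gRNA1 and higher with gRNA2 in 23, such as MYC, CCN1 and TXNIP, and the other way in 7, such as SLC5A3 and MRPS6. These 5 kept both calls in every setting run other than the 2-fold minimum, whereas 23 of the 30 lost a call against the control without 1 library. The count was 446 with the transcript length offset, 690 or 641 without gRNA1 replicates 1 or 2, 575 without gRNA2 replicate 2 and 1000 without gRNA2 replicate 3.

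Between the guides 22 lists passed, of which 21 are described, 12 higher and 10 lower with gRNA2, and 16 did so with an estimated correlation (adjusted p at most 0.0378). The lowest list p-values were those of histones, with 43 of 62 lower (54 adjusted over the list alone; adjusted p = 1.13e-52), G2 and mitosis, 29 of 36 lower (33 adjusted over the list alone; 1.64e-44), and the ATF4 list, 19 of 33 higher (21 higher and 1 lower adjusted over the list alone; 7.43e-36). MAPK pathway output had 12 of 30 higher (19 adjusted over the list alone; 3.38e-24), and S phase and DNA replication 16 of 33 lower (22 adjusted over the list alone; 2.69e-18). TGF-beta and YAP targets had 9 of 24 higher (11 adjusted over the list alone; 6.17e-14), and hypoxia and glycolysis 11 of 26 lower and 1 higher (16 and 1 adjusted over the list alone; 2.94e-13). Interferon-stimulated genes had 12 of 38 higher and 1 lower (15 and 1 adjusted over the list alone; 1.37e-07). NRF2 targets had 7 of 24 lower and 1 higher (12 and 2 adjusted over the list alone; 8.83e-07). EGFR family and ligands had 4 of 15 higher (8 higher and 1 lower adjusted over the list alone; 7.61e-06). KRAB zinc finger cofactors had 6 of 22 lower (8 lower and 1 higher adjusted over the list alone; 1.38e-05), and ribosomal proteins 5 of 83 lower and 1 higher (8 and 1 adjusted over the list alone; 3.64e-06). Apoptosis regulators had 6 of 29 higher and 1 lower (10 and 1 adjusted over the list alone; 0.00605). Antigen presentation had 2 of 18 higher (6 adjusted over the list alone; 0.00557) and known long noncoding RNAs 8 of 21 higher and 1 lower (8 and 3 adjusted over the list alone; median log2 0.07, mean -0.02, direction up, 0.00244). Passing with the preset correlation alone were nuclear oxidative phosphorylation (12 of 78 lower and 1 higher, 16 and 1 adjusted over the list alone; 3.45e-07, adjusted p = 0.0732 with an estimated correlation) and heat shock proteins (4 of 16 lower, 6 lower and 1 higher adjusted over the list alone; 0.00194, adjusted p = 0.107 with an estimated correlation). The same held for homologous recombination (1 of 28 lower and 1 higher, 5 and 2 adjusted over the list alone; 0.027, adjusted p = 0.291 with an estimated correlation), and sterol synthesis (3 of 24 higher, 5 adjusted over the list alone; 0.027, adjusted p = 0.0732 with an estimated correlation). The last were epithelial genes (2 of 26 higher and 2 lower, 3 and 2 adjusted over the list alone; 0.027, adjusted p = 0.532 with an estimated correlation) and mesenchymal genes (3 of 20 higher and 1 lower, 5 and 2 adjusted over the list alone; 0.0235, adjusted p = 0.343 with an estimated correlation). The other 12 lists did not pass between the guides (adjusted p between 0.0668 and 0.967).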

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

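The tests of the reads behind the target, of genomic DNA (in place of a test on olfactory receptor reads set before, which cannot tell the sources of those reads apart), of single libraries for the cell cycle and histone lists, and of GC content and length for those lists were chosen after the result was seen. The criteria of the other tests in this part were set before their own results. The GC and length correction was itself added after the data were seen, so its test on the long noncoding RNAs was not fixed before them.

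The libraries labelled gRNA1 and gRNA2 differed in 3 gene lists and 6 named genes that passed the threshold as lower with 1 guide and higher with the other, and in the test of the difference between the guides. On the log2 scale the median of the MAPK output list was 0.24 higher with gRNA2 than with gRNA1, that of the ATF4 and unfolded protein response list 0.22 higher, and that of the TGF-beta and YAP target list 0.11 higher. Against the control the median of this last list was -0.17 with gRNA1 but only 0.01 with gRNA2, where 5 of 24 members were higher and 2 lower. With an estimated correlation the MAPK call with gRNA1 (adjusted p = 0.169) and the TGF-beta and YAP call with gRNA2 (0.0858) ended, and all 3 differences held. The stress factor ATF3 was 0.91 higher with gRNA2 than with gRNA1 (adjusted p = 9.22e-07), MYC 0.79 higher (9.92e-08) and CCN1, a YAP target, 0.79 higher (1.63e-08). The EGFR ligand AREG was 0.72 higher (3.51e-05), the interferon-stimulated IFITM1 0.48 higher (8.45e-06) and the EGFR inhibitor ERRFI1 0.32 higher (3.69e-05). The ATF3 call with gRNA1 ended without control replicates 2 or 3, any gRNA1 library or gRNA2 replicate 2 (adjusted p between 0.0568 and 0.129), with DESeq2 (0.0718) and with the transcript length offset (0.485). That of AREG with gRNA1 ended without control replicates 2 or 3 or gRNA1 replicates 1 or 2 (0.0627 to 0.111) or with the length offset (0.0714), and that of ERRFI1 with gRNA1 without any control, gRNA1 replicates 2 or 3 or gRNA2 replicate 2 (0.0577 to 0.119) or with protein-coding genes alone (0.0537). The length offset ended the ERRFI1 calls with both guides (0.148 and 0.0697). The IFITM1 call with gRNA2 ended without control replicates 2 or 3, gRNA1 replicate 2 or gRNA2 replicates 1 or 2 (0.0549 to 0.142), with the length offset (0.0548) and with only the 2 groups compared (0.0522), and 35.3% of its 31-mers occur in other genes.

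Reads of TRIDDENT, summed over its transcripts, were not lower by 50% with either guide, though they were lower with gRNA1 before adjustment, and on few reads ENST00000571302.1 went from 1.54 ± 0.423 TPM to 0.78 ± 0.412 with gRNA1 and ENST00000649221.1 from 0.312 ± 0.0647 to 0.0387 ± 0.067 and 0.063 ± 0.0552. Too few reads to show a fall of the sum by 50% is argued against by the 95% interval of the fold, whose lower bound was 0.588 with gRNA1 and 0.753 with gRNA2. A single wrong label is argued against by 9 of 9 libraries correlating best with the other libraries of their own group. Reads shared with other transcripts stay open, since 12.61% of the 31-mers of the main transcript occur in other genes, above the 10% set in advance as little sharing and below the 50% set as much. That TRIDDENT, matched by a synonym, is not the RNA the guides target also stays open, as does a repressor that acts on only some of its transcripts or weakly, which may be the biological explanation, and neither was tested.

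Called long noncoding RNAs were higher in 92.8% of the calls with gRNA1 and in 93% with gRNA2. Genomic DNA, which lies evenly over genes, is argued against by 137 genes of the keratin-associated, beta-defensin and alpha interferon families, whose reads per kb in the guide libraries had an upper 95% bound at 0.721% of the median rise per kb of the higher long noncoding RNAs with gRNA1 and 0.606% with gRNA2, and 0 of the 141 and 159 rose by less than that bound. GC content and length as the whole cause are argued against by 80.3% and 86.5% higher calls after the correction. A low read level stays open as a part of the cause, since 70.6% (95% interval 62.7% to 77.7%) and 63.8% (55% to 72.1%) of the calls among protein-coding genes matched on level were also higher. As the whole cause it is argued against by a comparison outside the criterion set before, of 3417 genes of each class matched on level. Long noncoding RNA calls were 136 higher and 10 lower with gRNA1 and 153 and 12 with gRNA2. Those of protein-coding genes were 108 and 45, and 83 and 47. The share of reads in transcripts annotated as retained introns, an indirect sign of unspliced RNA, lay above all 3 controls in 6 of 6 guide libraries. More unspliced RNA and an effect of the guides on this class could add to the excess of higher calls and were not tested for these genes.

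The G2 and mitosis and histone lists were lower with gRNA2. A single gRNA2 library is argued against by the highest adjusted p of both lists without any 1 library, 2.92e-35 in camera with the preset correlation, and by the means of both lists lying below all 3 controls in all 3 libraries. With an estimated correlation, for which no library was left out, the adjusted p in camera was 0.000711 for G2 and mitosis and 0.00723 for histones. GC content and length are argued against by the medians after the correction, which kept 111.8% (from -0.34 to -0.38) and 104.3% (from -0.47 to -0.49) of their size. Slower division of these cells is a hypothesis that is consistent with these values, was found in the same data and was not tested, since it needs cell counts or DNA content, which the series does not hold. Growth conditions that differed between the cultures of each label were not tested, because the labels give no batch.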

How the results depend on the processing

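The correction for GC content and length was chosen after the data were seen; the other settings were chosen before. The numbers of genes called with gRNA1, with gRNA2, with both in the same direction and between the guides stayed within 1.5 times the reported 1391, 1659, 484 and 1222 with DESeq2, RLE scaling, a replicate block, fits of only the 2 groups compared and protein-coding genes alone. Without a filter on low counts the number for both guides was 756, of which 445 were among the 484, and the cause was not tested. With the transcript length offset the numbers were 538, 434, 104 and 446, of which 460, 388, 95 and 377 were among those reported, and the cause was not tested. With the GC correction they were 3166, 3481, 1453 and 2491, and the share higher fell from 49.4%, 43.8% and 59.9% to 30.7%, 30.2% and 27% in the first 3, with the cause not tested. A change of at least 2-fold, which removes the smaller changes by construction, left 97, 46, 21 and 30. An estimated correlation left 4 of 15 lists with gRNA1 and 16 of 25 with gRNA2; RLE scaling, a replicate block, protein-coding genes alone, the GC correction and each library left out gave 13 to 17 and 21 to 25 lists. Leaving out each library in turn gave 654 (gRNA1 replicate 2) to 1701 (gRNA2 replicate 1) genes with gRNA1 and 671 (gRNA2 replicate 2) to 1817 (gRNA1 replicate 3) with gRNA2. It gave 216 (control replicate 3) to 579 (gRNA2 replicate 1) with both, and 575 (gRNA2 replicate 2) to 1215 (control replicate 1) between the guides. The numbers below the reported ones by over 1.5 times also came without control replicates 1, 2 and 3 (gRNA1 826, 786 and 727; gRNA2 1023, 900 and 792; both 263 and 252), gRNA1 replicate 1 (gRNA1 756, both 299, between the guides 690), gRNA1 replicate 2 (both 256, between the guides 641) and gRNA2 replicate 2 (both 222). Fewer libraries give each test less power by construction. Of 219 results for named genes, 104 kept their direction and side of the threshold in every setting run for them. Of the rest, 112 lost the call under at least 1 setting, 105 of them with the length offset and 64 without some library, and 2 reversed. APEX1 with gRNA2 turned to a log2 change of 0.05 with the length offset and NEAT1 with gRNA1 to -0.02 with the GC correction, and the cause was not tested. With 36 to 62 reads per library, depth leaves a 95% interval of 0.588 to 0.943 for the target with gRNA1 and of 0.753 to 1.19 with gRNA2.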

Other observations

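Some genes outside the named set went opposite ways with the guides. PSAT1, an enzyme of serine synthesis, was lower with gRNA1 (log2 -0.2, adjusted p = 0.00749 in edgeR) and higher with gRNA2 (0.23, 0.00294). ASNS, asparagine synthetase, was also lower with gRNA1 (-0.25, 0.00255) and higher with gRNA2 (0.18, 0.0176), and both differed between the guides (0.43 each, adjusted p = 2.57e-05 and 3.86e-05). TXNIP, an inhibitor of thioredoxin, moved by -0.22 (adjusted p = 0.00182) and 0.61 (5.58e-07), and PSG4, a pregnancy-specific glycoprotein, by -0.24 (0.000964) and 0.17 (0.00914). The opposite way went SLC5A3, the myo-inositol transporter, at 0.5 (2.68e-05) and -0.33 (0.000985), and MRPS6, a mitochondrial ribosomal protein, at 0.54 (2.38e-06) and -0.25 (0.00207). The annotated spans of SLC5A3 and MRPS6 overlap on chromosome 21. The ASNS call with gRNA2 ended without control replicates 1, 2 or 3 (adjusted p = 0.0528, 0.0648 and 0.0509) or gRNA2 replicate 2 (0.105), and that with gRNA1 with the transcript length offset (0.069). These genes were chosen after their values were seen.

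The test of genes next to the target was chosen after the result was seen, and the others here before. If the guides acted broadly on genes around the target, those within 1 Mb would be called more often. Of 64 such genes 2 were called with gRNA1, DNASE1 (log2 0.24, adjusted p = 0.0212) and ADCY9 (0.18, 0.0488), and 0 with gRNA2 in edgeR, against 7.1% and 8.5% of the other genes. Fisher's exact test, one-sided, gave p = 0.947 and p = 1, so the genes within 1 Mb were, as a set, not called more often than others. The test cannot show an effect on only a few adjacent genes. The annotated span of ADCY9, positions 3953387 to 4116185, lies close to that of the target gene, whose highest position is 3950586. These are bounds of the spans, and the sites where transcription of the genes starts were not compared. With gRNA2 it was also higher but did not pass the threshold (log2 0.16, adjusted p = 0.0696 in edgeR).

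Olfactory receptor reads were higher in the guide libraries, 399 ± 2.74 RPM with gRNA1 and 387 ± 10.1 with gRNA2 against 317 ± 9.57 in the controls (n = 3). Of 385 such genes 245 had no reads in any library, so the sums come from the rest and not from the whole class. More unspliced RNA in the guide libraries is a candidate explanation. The share of reads of protein-coding genes in transcripts annotated as retained introns lay above all 3 controls in 6 of 6 guide libraries, at 7.19% ± 0.01 and 7.51% ± 0.0586 against 6.98% ± 0.02. The order of the guides is not the same in both measures, gRNA1 being higher in the first and gRNA2 in the second.

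Other splits of the libraries of 2 groups number 10 with the real one, too few for a share under 0.05, and in each case 1 split, the real one, gave as many calls. Genes with gRNA1 numbered 1391 against a highest other of 2, with gRNA2 1659 against 4, and between the guides 1222 against 2. Lists with gRNA1 numbered 15 against 7, and with gRNA2 25 against 15. For genes changed the same way by both guides, 2 of 100 splits of all 9 libraries gave as many as the real 484, so chance can be excluded at 0.05 as a random division of the libraries. The highest other, 491, kept the 3 groups whole with the libraries labelled gRNA2 in the place of the control, and splits that broke up a group gave at most 211. The splits thus show that the groups differ, and not that more genes are shared against the control than against another group.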
